A study of Mus musculus with 16 samples.

How the data were processed

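Bone marrow of NZM2410 mice was cultured in GM-CSF (20 ng/ml) and IL-4 (10 ng/ml), and dendritic cells were harvested on day 7, per the labels' protocols. Loxoribine (TLR7) and CpG (1 μg/ml, TLR9) or vehicle were given for 24 h. The labels give the loxoribine dose as 200 μmol/ml, a unit that could not be checked. RNA was sequenced with paired ends from TruSeq libraries, and the series' design text speaks of cells with high CD11c. The labels speak of triplicates, while 2 libraries per group were analysed here. Nothing in the sources used here says that the 2 libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

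Groups follow the source labels of the samples, which give 4 arms (WT, KO, ERKO OVX and Ex3a OVX) and 2 treatments. The genotype labels and descriptions go against the source labels in the vehicle groups of KO and ERKO OVX, which they call the null allele, and in both Ex3a OVX groups, which they call the ERα short allele. Reads summed per gene cannot tell the Esr1 alleles apart, so the allele of an arm was not checked here, and the report gives the levels that bear on whether vehicle and agonist libraries of an arm belong together.

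The deposited table gives FPKM (fragments per kilobase of transcript per M mapped fragments) for 24001 gene rows and 16 libraries. The submitters' processing notes name cutadapt, FastQC, STAR, HTSeq, DESeq2 and the mouse genome build mm10, without versions. The program that made the FPKM values is not given in the sources used here. FPKM divides by length and library total, so counts of fragments are lost, and a library in which a few genes take much of the total shows lower values for all others. The table's own name speaks of counts, but its values are not whole numbers, and the sums of FPKM per library were 481738 to 522287 in the unoperated arms and 612322 to 696321 in the ovariectomized arms. Depth was estimated from the steps between low values of 4190 single-transcript genes, at 37.6 to 44.1 M fragments (M, mega) per unoperated library and 17.8 to 24.0 M per ovariectomized library. The estimate is rough, since 43.4 to 50.7% of the low values lay within 0.1 of a whole number of fragments.

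Of the rows, 5724 were at 0 in all libraries. A choice made after the values were seen left out 1229 rows of small structural and micro RNAs. Symbols of 27 rows had been turned into dates by spreadsheet software. They were left as dates and not named, and 4 of them can stand for 2 genes. A zero was taken as missing where every other library of at least 12 above 0 held 5 FPKM or more, which removed 5 zeros in Actr3, Ccl22, Hnrnpd and Jak2. Ccl22 was missing in both agonist libraries of KO and was not tested there, so comparisons with that group had 11345 genes and the others 11346. Genes were tested that reached 1 FPKM in at least 2 libraries.

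The tests had been set for counts, with limma on log values as the stated fallback, and the fallback was used because the values are FPKM. The limma trend method (limma 3.58.1 in R 4.3.3, robust empirical Bayes) was fitted to log2(FPKM + 1) with 1 coefficient per group, and p-values were adjusted by Benjamini and Hochberg's method within each comparison, with a threshold of 0.05. Before averaging, the 2 libraries of each group were compared with sampling noise. In genes with 5000 or more fragments the median variance over the sampling variance was 1.17, 1.46, 0.924 and 1.39 in the ERKO OVX agonist, ERKO OVX vehicle, Ex3a OVX vehicle and Ex3a OVX agonist pairs, and 3.07, 5.53, 2.51 and 5.09 in the KO vehicle, KO agonist, WT vehicle and WT agonist pairs (2000 bootstrap draws for each interval). The 95% interval excluded 1 for ERKO OVX vehicle (1.06 to 1.93) and not for the other ovariectomized pairs. Each ovariectomized pair was therefore averaged and counted as 1 sample, a departure from the design set in advance, in which 16 libraries would have entered. The fit had 12 samples and 4 residual degrees of freedom, all from the unoperated groups, so the lone ovariectomized samples were assumed to vary like these and had no replicate check of their own.

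The comparisons were the agonist response in each arm, KO against WT and Ex3a OVX against ERKO OVX in each treatment, the difference of the agonist response within each of these pairs of arms, and the vehicle groups of ERKO OVX against KO and of Ex3a OVX against WT. A comparison of the agonist response between ERKO OVX and KO was added after the data were seen. The gene lists were tested with camera (preset correlation 0.01, lists of at least 5 tested genes) and again with an estimated correlation. They held interferon-stimulated genes, inflammatory cytokines and chemokines, dendritic cell maturation, MHC class II and class I presentation, NF-kB feedback, the endosomal TLR pathway, cell cycle, estrogen response and receptors, sterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, IL-4 response, macrophage, conventional and plasmacytoid dendritic cell, neutrophil and granulocyte precursor, B cell, T and NK cell, mast cell and basophil, eosinophil, erythroid, fibroblast and stroma, and immediate early and stress genes. Of 477 members, 6 had no row and 5 were matched by an older symbol, and 8 genes were in 2 lists. The median, the mean and the camera direction of a list differed in sign in 32 of 273 tests, 0 of them past the camera threshold.

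Genes were named by a rule: per comparison, the 10 largest rises and 10 largest falls past the threshold with a group mean of at least 5 FPKM and no overlap between the libraries of the compared groups, leaving out predicted genes; the 4 members of each list with the lowest p; and Esr1, Il6, Il12b, Ifnb1, Il10, Tnf, Cxcl10, Ccl5, Il23a, Irf4, Irf7, Tlr7 and Tlr9. Interactions carried no demand on overlap. Some genes that meet the rule are not reported here. The groups, comparisons, tests, lists and this rule were fixed before the data were examined, except for the departures named here and the minimum of 5, which had been set in counts per M. Gene positions, from an mm10 annotation, were known for 11274 of the 11346 tested genes, and the others were left out where position was tested. Beside an overlap of 2 call sets stands the number expected for independent lists, the product of both counts over the genes tested in both.

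Tested on simulated data with 11346 genes, the fit recovered 100% of 2-fold changes in the agonist comparison of WT, of ERKO OVX and in the interaction of KO and WT, and 90%, 52% and 49% of 1.3-fold changes in the same order. Alternatives covered the pseudocount (0.1 and 5), the filter on low values, the groups in the fit, a replicate block, limma without robust estimation, limma's treat test for 1.5-fold, leaving out each library, fry in place of camera, and lists without shared genes. Added after the data were seen were the fit of 16 libraries, median-of-ratios scaling, a filter of 5 FPKM, small RNA rows kept and crossed pairing. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 in R, did the rest.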

Results

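Gene expression was measured by RNA-seq in dendritic cells grown from the bone marrow of NZM2410 mice, an inbred strain prone to lupus. The comparisons ask how the form of estrogen receptor α a mouse carries goes with expression in these cells before and after TLR stimulation. Marrow was cultured for 7 days with GM-CSF and IL-4, and the cells then received for 24 h either vehicle or loxoribine and CpG DNA, agonists of the endosomal receptors TLR7 and TLR9. The 16 libraries formed 4 arms of 2 vehicle and 2 agonist libraries each. The WT arm carried the intact receptor and the KO arm the truncated receptor called ERα short, and neither had surgery. In the ERKO OVX arm (ERα short) and the Ex3a OVX arm (no ERα) the mice had been ovariectomized and given a 0.25 mg, 90-day estradiol pellet. The values were FPKM, with an estimated depth of 37.6 to 44.1 M fragments in unoperated libraries and 17.8 to 24.0 M in ovariectomized ones. The 2 libraries of each ovariectomized group differed by about sampling noise, so each pair was averaged and counted as 1 sample, leaving 12 samples. Values of unoperated groups are given as mean ± SD (n = 2), and those of ovariectomized groups as the mean of the pair with no SD. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, with the standard error of the limma fit. For the ovariectomized groups that error assumes that they vary like the unoperated ones. Across genes, Pearson's r between libraries was 0.9982 to 0.9991 within a group, 0.9810 to 0.9929 between treatments of 1 arm, 0.9619 to 0.9839 between arms of the same surgery state and 0.9038 to 0.9447 across surgery states, where genes are not independent replicates.

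Esr1, which encodes estrogen receptor α (chromosome 10, 4611989 to 5005633, mm10), was the targeted gene and was low everywhere. Its FPKM in the 2 vehicle libraries was 1.21 and 1.38 in WT, 2.47 and 2.57 in KO, 1.02 and 0.982 in ERKO OVX and 0.347 and 0.283 in Ex3a OVX. After the agonists it was 0.937 and 0.684, 2.01 and 1.77, 1.12 and 1.16 and 0.364 and 0.317 in the same order. Esr1 was higher in KO than in WT by 0.62 ± 0.08 log2 units with vehicle and 0.68 ± 0.08 with agonists (limma adjusted p = 8.13e-05 and 5.23e-05). It was lower in Ex3a OVX than in ERKO OVX, with log2 fold changes of -0.61 ± 0.11 and -0.67 ± 0.11 (limma adjusted p = 0.00112 and 4.70e-04). Values per gene cannot separate a truncated or disrupted transcript from an intact one, so these levels do not check which allele a library carries. Genotype labels name the null allele for KO and ERKO OVX vehicle libraries and ERα short for Ex3a OVX. Both contradict the source labels used here. By the genotype labels the agonist libraries of KO and ERKO OVX would share an allele with Ex3a OVX and not with their own vehicle libraries. C1qa, picked below by comparing these arms, was at 3.27 ± 0.252 and 2.34 ± 0.132 FPKM with vehicle and agonists in KO. ERKO OVX had 2.43 and 2.48 and Ex3a OVX 116 and 84.1. These levels set both treatments of KO and of ERKO OVX apart from Ex3a OVX. They do not tell KO from ERKO OVX and cannot check the allele.

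In WT cells the agonists raised cytokines and chemokines of acute inflammation the most. Il1b, the secreted pyrogen interleukin 1β, went from 36.9 ± 8.31 to 692 ± 14.3 FPKM (log2 fold change 4.21 ± 0.15, limma adjusted p = 9.01e-06). Il6 (chromosome 5, 30013114 to 30019975), which drives the acute phase response, went from 16.9 ± 0.852 to 190.2 ± 2.18 FPKM (3.41 ± 0.05, adjusted p = 4.56e-11). Il12b (chromosome 11, 44400063 to 44414677), the shared subunit of interleukins 12 and 23, went from 26.8 ± 1.76 to 308 ± 2.65 FPKM (3.47 ± 0.04, adjusted p = 3.63e-11). The neutrophil-attracting chemokines Cxcl1 (4.36), Cxcl2 (3.35) and Cxcl5 (3.28), the prostaglandin synthase Ptgs2 (3.84), Il1a (3.82) and Tnf (3.47) and the acute phase protein Saa3 (3.18) were the other large rises. Among the largest falls were those of the monocyte chemokine receptor Ccr2 (-1.89), the guanine deaminase Gda (-1.84) and Ceacam15 (-1.80). Of 11346 genes tested, 3499 rose and 3071 fell at an adjusted p of 0.05, of which 178 and 90 by over 2-fold. Counts over 2-fold here and below depend on the 1 FPKM added before the logarithm, and these 268 genes became 505 with 0.1 and 122 with 5 FPKM added. In limma's treat test 524 changed by more than 1.5-fold.

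Gene lists fixed before the values were read are described by the number of members past the test over all genes, and the count adjusted over the list alone is given where it differs. Inflammatory cytokines and chemokines had 20 of 30 higher and 4 lower (21 and 4 adjusted over the list alone, camera adjusted p = 1.02e-06, adjusted p = 0.284 with an estimated correlation), with Ccl3 (2.99) and Cxcl3 (1.91) beside the genes above. Dendritic cell maturation genes had 17 of 20 higher and 1 lower (camera adjusted p = 7.00e-09, adjusted p = 0.41 with an estimated correlation), led by the costimulatory receptor Cd40 (2.47), the actin bundler Fscn1 (1.43) and Cd80 (1.19). The NF-kB feedback genes had 16 of 17 higher and 0 lower (camera adjusted p = 5.46e-11, adjusted p = 0.14 with an estimated correlation), among them Nfkbiz (2.98) and Socs3 (2.51) and the cytokine mRNA nuclease Zc3h12a (1.97). Cell cycle genes had 2 of 30 higher and 23 lower (camera adjusted p = 9.34e-06, adjusted p = 0.455 with an estimated correlation), with Mcm5 (-0.76) and Mcm7 (-0.95) of the replicative helicase lower and the thymidylate synthase Tyms (1.04) higher. The estrogen response list had 2 of 16 higher and 12 lower (camera adjusted p = 8.75e-04, adjusted p = 0.14 with an estimated correlation), with the cyclin Ccnd1 (-1.61) and the angiogenic factor Vegfa (-1.20) lower. Sterol biosynthesis had 17 of 21 higher and 3 lower (17 and 4 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.14 with an estimated correlation), with Idi1 (1.07) higher and Dhcr7 (-0.98) lower. Glycolysis genes had 3 of 21 higher and 11 lower (camera adjusted p = 0.0362, adjusted p = 0.686 with an estimated correlation), including the lactate carrier Slc16a3 (-0.46). Oxidative phosphorylation genes had 2 of 25 higher and 12 lower (camera adjusted p = 0.013, adjusted p = 0.41 with an estimated correlation), including Sdhd (-0.27) of succinate dehydrogenase. IL-4 response genes had 4 of 18 higher and 10 lower (camera adjusted p = 0.0489, adjusted p = 0.284 with an estimated correlation), with the mannose receptor Mrc1 (-0.89) and Arg1 (-1.14) lower and the chemokines Ccl17 (1.48) and Ccl22 (1.78) higher. Interferon-stimulated genes split, with 8 of 32 higher and 15 lower (camera adjusted p = 0.0946). Ifit1 (0.61) rose while the RNA-sensing enzyme Oas3 (-0.60) and the interferon regulator Irf7 (-0.23) fell. The interferon gene Ifnb1 did not pass the test (0.07), and the receptors themselves were lower, Tlr7 (-0.32) and Tlr9 (-0.46).

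Cytokine genes were among the largest agonist rises in KO too. Il1b went from 110.4 ± 3.48 to 1094 ± 23.5 FPKM (3.30 ± 0.15, limma adjusted p = 2.94e-05). Il6 went from 26.5 ± 0.00728 to 205 ± 15.7 FPKM (2.90 ± 0.05) and the macrophage chemokine Ccl3 from 56.8 ± 2.93 to 809 ± 52.1 FPKM (3.81 ± 0.06). Further large rises were in Ptgs2 (4.13), Il1a (3.72), Cxcl1 (3.53), Tnf (3.36) and Saa3 (3.31). The largest falls included those of the matrix protease Mmp19 (-1.96), Ceacam15 (-1.86) and Ccr2 (-1.85) and the immediate early factor Fos (-1.49). The cytokine list had 24 of 30 higher and 2 lower (25 and 2 adjusted over the list alone, camera adjusted p = 4.54e-11, adjusted p = 0.147 with an estimated correlation), with Il12b (2.73) and Cxcl3 (2.29) among its higher members. Maturation genes had 17 of 20 higher and 2 lower (camera adjusted p = 8.16e-08, adjusted p = 0.394 with an estimated correlation), as in Cd40 (1.61) and Fscn1 (1.01). NF-kB feedback genes had 16 of 17 higher and 0 lower (camera adjusted p = 2.63e-11, adjusted p = 0.133 with an estimated correlation), as in Socs3 (2.58) and Nfkbiz (2.47). Cell cycle genes had 2 of 30 higher and 28 lower (camera adjusted p = 2.07e-08, adjusted p = 0.381 with an estimated correlation), with Mcm5 (-0.79) and Mcm7 (-0.89) lower. The estrogen response list had 1 of 16 higher and 11 lower (1 and 12 adjusted over the list alone, camera adjusted p = 7.08e-04, adjusted p = 0.133 with an estimated correlation), with Ccnd1 (-1.41) and Vegfa (-1.19) lower. Sterol biosynthesis had 16 of 21 higher and 2 lower (16 and 3 adjusted over the list alone, camera adjusted p = 8.65e-04, adjusted p = 0.133 with an estimated correlation), with Idi1 (0.79) and Fdps (0.37) higher. In all, 2942 genes rose and 2873 fell of 11345, 130 and 63 by over 2-fold. The treat test placed 358 past 1.5-fold. Of the genes that rose over 2-fold, 114 were shared with WT against 2.03 for independent lists, as were 45 that fell against 0.5. Fold changes of the 2 arms correlated across genes at r = 0.92.

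The agonist response itself differed between KO and WT in 790 of 11345 genes by the interaction test, 261 with a more positive change in KO and 529 with a more negative one. Ccl7, a monocyte chemokine, fell by 0.32 log2 units in WT and rose by 1.19 in KO (difference 1.51 ± 0.06, limma adjusted p = 2.69e-06). Differences to the same side were found for the chemokines Ccl4 (1.47), Ccl2 (1.05) and Ccl3 (0.81), the collagenase Mmp13 (1.05) and the transcription factor Maf (1.11). Cxcl5 rose by 3.28 in WT and 2.12 in KO (-1.17 ± 0.07). Rises were smaller in KO also for Cav1 (-0.92), Cd40 (-0.86), Cd70 (-0.82), Il12b (-0.74), Il6 (-0.51) and Il23a (-0.52). With agonists Il12b was higher in KO (0.82), and Il6 (0.11) and Il23a (0.003) missed the test. Maturation genes had 0 of 20 more positive and 15 more negative in KO (0 and 16 adjusted over the list alone, camera adjusted p = 1.09e-14, adjusted p = 0.331 with an estimated correlation). NF-kB feedback genes had 1 of 17 more positive and 11 more negative (1 and 12 adjusted over the list alone, camera adjusted p = 1.47e-07, adjusted p = 0.331 with an estimated correlation), as in Nfkbiz (-0.51) and Zc3h12a (-0.45). MHC class II genes had 0 of 12 more positive and 4 more negative (0 and 7 adjusted over the list alone, camera adjusted p = 2.60e-04, adjusted p = 0.327 with an estimated correlation), as in H2-Oa (-0.46) and Ciita (-0.23). Interferon-stimulated genes had 6 of 32 more positive and 0 more negative (13 and 2 adjusted over the list alone, camera adjusted p = 8.70e-07, adjusted p = 0.331 with an estimated correlation), as in Usp18 (0.27) and Oas3 (0.21). Neutrophil and granulocyte precursor genes had 4 of 18 more positive and 0 more negative (4 and 2 adjusted over the list alone, camera adjusted p = 0.0308, adjusted p = 0.55 with an estimated correlation), as in Lcn2 (0.82) and Camp (0.30). The cytokine list split 6 to 5 of 30, or 6 to 9 adjusted over the list alone (camera adjusted p = 0.553). The 5 genes Ccl7, Ccl4, Maf, Mmp13 and Ccl2 exceeded 2-fold upward and 1, Cxcl5, downward. The 5 past 1.5-fold in the treat test were Ccl7, Cxcl5, Mmp13, Ccl2 and Cav1. The count fell to 404 without the filter on low values and to between 431 and 651 when single libraries were left out.

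In the ERKO OVX arm, with the same ERα short receptor after ovariectomy and an estradiol pellet, cytokine genes rose from higher vehicle levels. Il6 went from 86.8 to 316 FPKM (1.85 ± 0.07, limma adjusted p = 6.11e-07), and its vehicle level was above that of KO by 1.68 ± 0.06 log2 units. Il1a, a cell-associated alarm cytokine, went from 161 to 793 FPKM (2.29 ± 0.13). Other large rises were in Cxcl2 (2.01) and Cxcl1 (1.96), the granulocyte growth factor Csf3 (1.96), Ccl3 (1.86), Il12a (1.66) and Tnf (1.66). Among its largest falls were those of the sugar phosphate exchanger Slc37a2 (-0.97), H2-Q7 (-0.94), the ectonucleotidase Nt5e (-0.91) and the lipid carrier Fabp4 (-0.86). Cytokines and chemokines had 21 of 30 higher and 1 lower (camera adjusted p = 8.87e-10, adjusted p = 0.149 with an estimated correlation), with Cxcl3 (1.28) also higher. NF-kB feedback had 17 of 17 higher and 0 lower (camera adjusted p = 3.06e-12, adjusted p = 0.117 with an estimated correlation), as in Nfkbiz (1.20) and Zc3h12a (1.13). Maturation genes had 6 of 20 higher and 4 lower (camera adjusted p = 0.529), with the inhibitory ligand Cd274 (0.65) and Cd40 (0.70) higher, and the median was -0.01 against a mean of 0.06. Oxidative phosphorylation genes had 0 of 25 higher and 23 lower (camera adjusted p = 7.04e-10, adjusted p = 0.117 with an estimated correlation), as in Sdhd (-0.32) and Atp5o (-0.28). MHC class II genes had 0 of 12 higher and 9 lower (0 and 11 adjusted over the list alone, camera adjusted p = 6.64e-05, adjusted p = 0.117 with an estimated correlation), as in H2-Aa (-0.23) and Cd74 (-0.15). MHC class I genes had 1 of 14 higher and 5 lower (camera adjusted p = 0.031, adjusted p = 0.526 with an estimated correlation), as in the immunoproteasome subunit Psmb8 (-0.35). Glycolysis genes had 2 of 21 higher and 11 lower (2 and 12 adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.526 with an estimated correlation), as in Pkm (-0.43) and Tpi1 (-0.35). Cell cycle genes had 1 of 30 higher and 12 lower (camera adjusted p = 0.0148, adjusted p = 0.526 with an estimated correlation), with Pcna (-0.44) lower and Mki67 (0.44) higher. The estrogen response list had 0 of 16 higher and 5 lower (camera adjusted p = 0.0127, adjusted p = 0.149 with an estimated correlation), with Igf1 (-0.51) and Ccnd1 (-0.41) lower. In all 2082 genes rose and 2176 fell, of which 31 rose over 2-fold and 1 fell over 2-fold. The latter was Gm12238, a predicted gene named after its values were seen and listed at 0 in both treated libraries. In the treat test 31 genes were past 1.5-fold. Of the genes over 2-fold higher, 30 had also risen over 2-fold in WT against 0.486 for independent lists. Across genes, r with the WT response was 0.62.

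In the Ex3a OVX arm, without ERα, the largest rise of a named gene was that of Cd300e (chromosome 11, 115051917 to 115066676), an activating receptor of monocytes, from 0.511 to 13.9 FPKM (3.30 ± 0.08, limma adjusted p = 4.51e-08). Il10 (chromosome 1, 131019845 to 131024970), an anti-inflammatory cytokine, went from 1.41 to 11.5 FPKM (2.38 ± 0.13, adjusted p = 3.18e-06). Il12b went from 44.9 to 187 FPKM (2.03 ± 0.05) and Il6 from 46.8 to 156 FPKM (1.72 ± 0.07). Tnf went from 90.4 and 93.1 to 173 and 169 FPKM but missed the test (0.89 ± 0.29, adjusted p = 0.0738), with an error from unoperated libraries. Cxcl10 was at 203 and 192 FPKM. The largest falls included Ear3 (-1.63), Ccnd1 (-1.52), Trem2 (-1.40), Fabp4 (-1.37), Clec10a (-1.31) and Mrc1 (-1.24). Interferon-stimulated genes had 17 of 32 higher and 1 lower (18 and 1 adjusted over the list alone, camera adjusted p = 2.54e-04, adjusted p = 0.333 with an estimated correlation), as in Ifit1 (0.60) and Isg15 (0.45). The cytokine list had 17 of 30 higher and 2 lower (20 and 3 adjusted over the list alone, camera adjusted p = 4.35e-06, adjusted p = 0.284 with an estimated correlation), with Ccl3 (1.36) also higher. Maturation genes had 15 of 20 higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 1.86e-06, adjusted p = 0.333 with an estimated correlation), as in Cd40 (0.88) and Fscn1 (0.56). NF-kB feedback genes had 14 of 17 higher and 2 lower (camera adjusted p = 9.24e-07, adjusted p = 0.224 with an estimated correlation), as in Nfkbiz (1.12) and Socs3 (0.76). MHC class II genes had 0 of 12 higher and 11 lower (1 and 11 adjusted over the list alone, camera adjusted p = 1.67e-06, adjusted p = 0.0982 with an estimated correlation), including the invariant chain Cd74 (-0.33). Cell cycle genes had 2 of 30 higher and 16 lower (2 and 20 adjusted over the list alone, camera adjusted p = 4.86e-06, adjusted p = 0.333 with an estimated correlation), as in Birc5 (-0.67) and Plk1 (-0.69). The estrogen response list had 1 of 16 higher and 10 lower (camera adjusted p = 4.24e-05, adjusted p = 0.0982 with an estimated correlation), as in Igf1 (-0.93) and Rara (-0.64). IL-4 response genes had 4 of 18 higher and 11 lower (5 and 11 adjusted over the list alone, camera adjusted p = 5.72e-04, adjusted p = 0.115 with an estimated correlation), with Ccl6 (-1.22) and Mrc1 lower. Macrophage genes had 3 of 17 higher and 11 lower (camera adjusted p = 0.0332, adjusted p = 0.469 with an estimated correlation), with Trem2 lower and Marco (1.47) and Emr1 (1.14) higher. In all 2168 genes rose and 2070 fell, 45 and 30 by over 2-fold. The treat test placed 84 past 1.5-fold. Of those over 2-fold higher, 22 had risen over 2-fold in WT against 0.706 for independent lists (r across genes 0.50).

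All 4 arms shared part of their rises. Acpp, Ccl3, Ccl4, Fabp3, Il12a, Il1a, Il1b, Il6, Lox, Nfkbiz, Pim2 and Ppap2a, 12 in number, rose over 2-fold in every arm. Without a demand on size, 527 genes were called higher and 596 lower in all 4 arms.

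**Figure D1:**
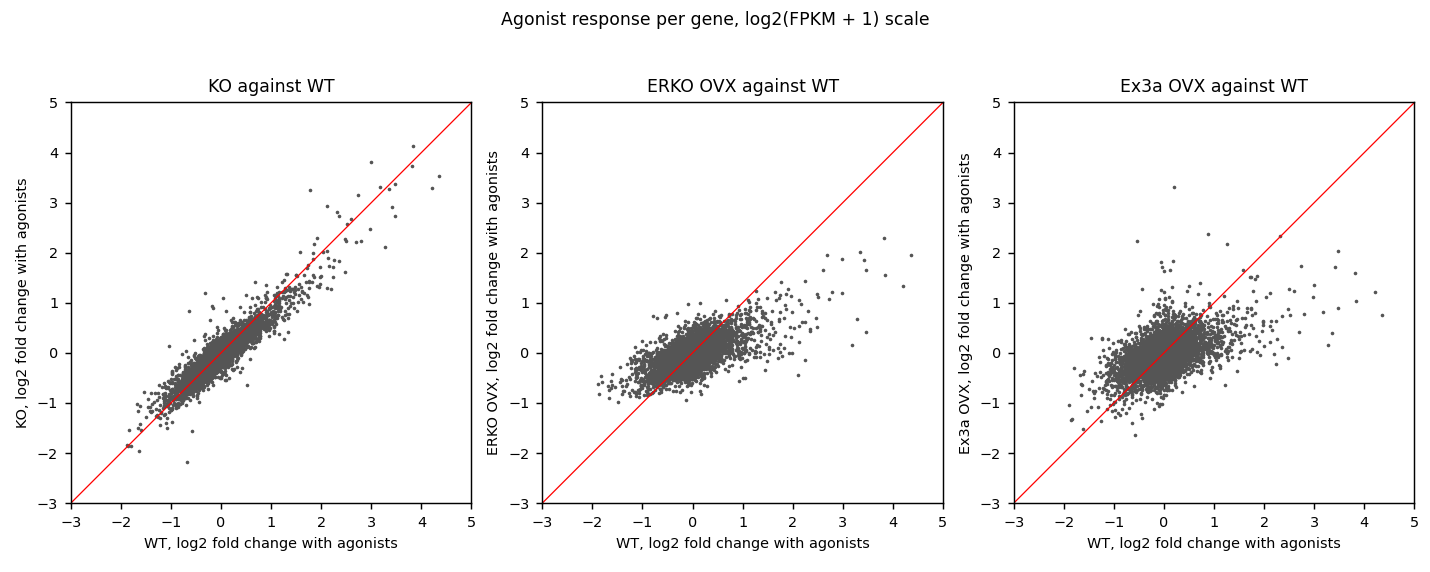
Log2 fold change (log2(FPKM + 1) scale) of each tested gene after TLR7 and TLR9 agonists, in KO, ERKO OVX and Ex3a OVX (vertical axes) against WT (horizontal axis), with the line of equal change in red. For genes that rose over 2-fold in WT, most points lie below it, with a median ratio of log2 fold changes to those of WT of 0.814 in KO, 0.351 in ERKO OVX and 0.288 in Ex3a OVX (r across genes 0.92, 0.62 and 0.50).

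**Figure D2:**
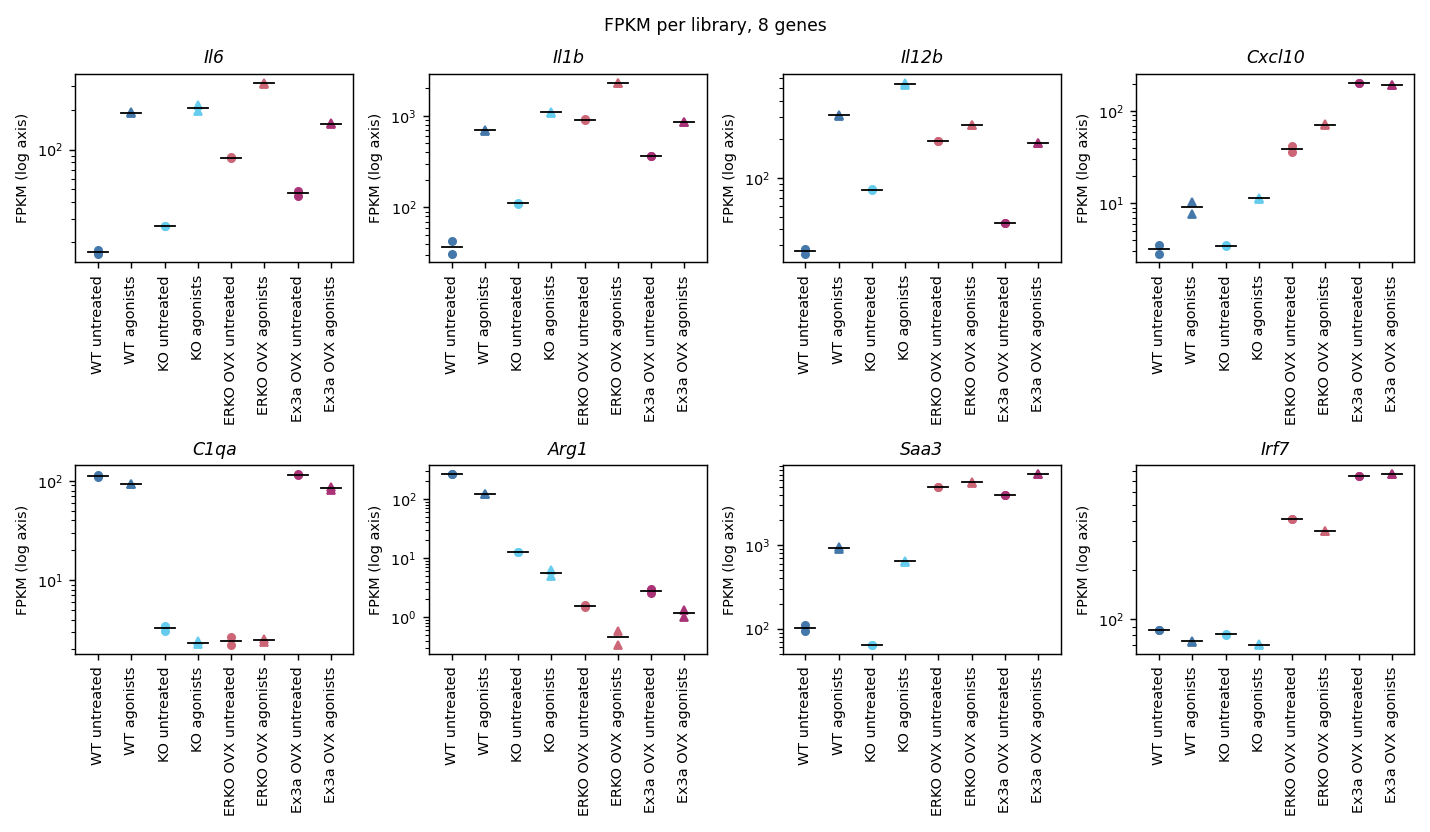
FPKM per library (log axes) of Il6, Il1b, Il12b, Cxcl10, C1qa, Arg1, Saa3 and Irf7 in the 4 arms, with circles for vehicle, triangles for agonists and a bar at the mean of the 2 libraries. Vehicle Il6 was 16.9 FPKM in WT and 86.8 in ERKO OVX, and C1qa was 113, 3.27, 2.43 and 116 FPKM in vehicle WT, KO, ERKO OVX and Ex3a OVX.

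Between the 2 ovariectomized arms, which differ by the receptor, the agonist response differed in 3560 of 11346 genes, 1894 more positive in Ex3a OVX and 1666 more negative. Cd300e (2.70 ± 0.11, limma adjusted p = 3.97e-06), Il10 (1.85 ± 0.19) and Il12b (1.62 ± 0.08) responded more in Ex3a OVX, as did the dicarboxylate transporter Slc13a3 (2.05) and Fcrls (1.66). The chemokines Cxcl2 (-1.61), Cxcl1 (-1.19) and Cxcl10 (-0.94) and the granulocyte growth factor Csf3 (-1.55) responded less. The inflammasome sensor Nlrp3 rose by 1.01 in ERKO OVX and fell by 0.31 in Ex3a OVX, a difference of -1.32 ± 0.08. Cytokines and chemokines had 6 of 30 more positive and 14 more negative (6 and 15 adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.478 with an estimated correlation). NF-kB feedback genes had 1 of 17 more positive and 7 more negative (2 and 7 adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.478 with an estimated correlation), as in Icosl (-0.73) and Zc3h12a (-0.58). Oxidative phosphorylation genes had 18 of 25 more positive and 0 more negative (22 and 0 adjusted over the list alone, camera adjusted p = 5.03e-09, adjusted p = 0.304 with an estimated correlation), a list for which the agonist test alone had 6 higher and 1 lower in Ex3a OVX. Interferon-stimulated genes had 13 of 32 more positive and 3 more negative (14 and 3 adjusted over the list alone, camera adjusted p = 0.00594, adjusted p = 0.478 with an estimated correlation), as in Irf7 (0.29). Maturation genes had 11 of 20 more positive and 2 more negative (camera adjusted p = 0.0047, adjusted p = 0.544 with an estimated correlation), as in Tnfsf4 (0.76) and Ccr7 (0.64). MHC class I genes had 5 of 14 more positive and 0 more negative (7 and 0 adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.478 with an estimated correlation), as in Psmb8 (0.41). Glycolysis genes had 12 of 21 more positive and 2 more negative (camera adjusted p = 0.0047, adjusted p = 0.478 with an estimated correlation), as in Tpi1 (0.44) and Pkm (0.40). Sterol biosynthesis genes had 8 of 21 more positive and 0 more negative (9 and 2 adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.342 with an estimated correlation), as in Mvd (0.60) and Fdps (0.35). The estrogen response list had 2 of 16 more positive and 6 more negative (2 and 7 adjusted over the list alone, camera adjusted p = 0.0392, adjusted p = 0.342 with an estimated correlation), as in Ccnd1 (-1.11) and Rara (-0.67). IL-4 response genes had 3 of 18 more positive and 7 more negative (3 and 8 adjusted over the list alone, camera adjusted p = 0.0302, adjusted p = 0.342 with an estimated correlation), as in Tgm2 (-1.05) and Ccl6 (-0.94). Over 2-fold were 31 genes upward and 21 downward, and 26 were past 1.5-fold in the treat test. With 16 separate libraries the count was 5534.

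KO and WT cells, which differ by the receptor and had no surgery, differed in C1q and other macrophage genes in both treatments. C1qa (chromosome 4, 136895916 to 136898844), a chain of the complement component that binds immune complexes, was at 113 ± 3.34 FPKM in vehicle WT and 3.27 ± 0.252 in vehicle KO (-4.74 ± 0.05, limma adjusted p = 1.99e-12). C1qb (-3.85) and C1qc (-4.18), its neighbours on the same chromosome, were lower too. Arg1 (chromosome 10, 24915207 to 24927470), the arginine-degrading enzyme of alternatively activated macrophages, was at 262 ± 0.465 FPKM in WT and 12.8 ± 0.110 in KO (-4.26 ± 0.07, adjusted p = 9.36e-11). It lies within 20 Mb of Esr1 on chromosome 10. The IL-4-induced Retnla (-4.00), the platelet chemokines Ppbp (-3.63) and Pf4 (-2.79), the iron exporter Slc40a1 (-3.28) and the chemokine Ccl7 (-2.97) were also lower. Higher in KO were the protease inhibitor Serpinb1a (2.67), the calcium-binding alarm protein S100a9 (2.32), Il1b (1.57) and Il12b (1.56) and the monoamine oxidase Maob (1.67). With agonists C1qa (-4.81), Arg1 (-4.19) and Retnla (-4.11) and the matrix glycoprotein Thbs1 (-3.03) were lower. S100a9 (3.49), Perp (1.62), which lies within 20 Mb of Esr1 as well, and the scavenger receptor Marco (1.44) were higher.

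Cell cycle genes were higher in KO cells, with 29 of 30 higher and 0 lower (29 and 1 adjusted over the list alone, camera adjusted p = 4.84e-11, adjusted p = 0.377 with an estimated correlation) in vehicle, as in Ccnb2 (1.21) and Birc5 (1.12) of mitosis. With agonists they had 28 of 30 higher and 0 lower (camera adjusted p = 9.86e-12, adjusted p = 0.374 with an estimated correlation), as in Birc5 (0.93) and Plk1 (0.88). Sterol biosynthesis genes had 20 of 21 higher and 0 lower (camera adjusted p = 7.53e-07, adjusted p = 0.0652 with an estimated correlation) in vehicle, as in Idi1 (1.10) and Cyp51 (0.64). After agonists the sterol list had 19 of 21 higher and 0 lower (camera adjusted p = 7.70e-08, adjusted p = 0.0486 with an estimated correlation). IL-4 response genes had 2 of 18 higher and 12 lower (camera adjusted p = 5.25e-06, adjusted p = 0.0652 with an estimated correlation) in vehicle, including Mgl2 (-2.76) and Tgm2 (-1.87). After agonists the IL-4 list had 1 of 17 higher and 13 lower (camera adjusted p = 7.77e-07, adjusted p = 0.0486 with an estimated correlation). Macrophage genes had 4 of 17 higher and 13 lower (camera adjusted p = 1.54e-04, adjusted p = 0.413 with an estimated correlation) in vehicle, with the lysosomal Gpnmb (-0.93) lower beside the C1q genes. After agonists the macrophage list had 4 of 17 higher and 13 lower (camera adjusted p = 3.64e-04, adjusted p = 0.374 with an estimated correlation). Glycolysis genes had 2 of 21 higher and 17 lower (camera adjusted p = 8.25e-07, adjusted p = 0.413 with an estimated correlation) in vehicle, as in the glucose transporter Slc2a1 (-0.67) and Hk2 (-0.72). With agonists they had 2 of 21 higher and 18 lower (camera adjusted p = 9.14e-07, adjusted p = 0.374 with an estimated correlation), as in Pkm (-0.53) and Slc16a3 (-0.51). Maturation genes had 15 of 20 higher and 3 lower (16 and 3 adjusted over the list alone, camera adjusted p = 1.07e-05, adjusted p = 0.439 with an estimated correlation) in vehicle, among them Cd40 (1.35) and Fscn1 (1.20). After agonists the maturation list had 11 of 20 higher and 4 lower (12 and 4 adjusted over the list alone, camera adjusted p = 0.0293, adjusted p = 0.739 with an estimated correlation), with Fscn1 (0.77) higher and Cd274 (-0.50) lower. NF-kB feedback genes had 15 of 17 higher and 2 lower (camera adjusted p = 6.54e-06, adjusted p = 0.377 with an estimated correlation) in vehicle, as in Traf1 (0.90) and Birc3 (0.55). After agonists the NF-kB list had 12 of 17 higher and 2 lower (camera adjusted p = 0.002, adjusted p = 0.374 with an estimated correlation). Interferon-stimulated genes had 21 of 32 higher and 7 lower (camera adjusted p = 0.00269, adjusted p = 0.439 with an estimated correlation) in vehicle, as in Isg15 (0.55). With agonists they had 23 of 32 higher and 6 lower (camera adjusted p = 1.18e-05, adjusted p = 0.374 with an estimated correlation), as in Herc6 (0.82). The cytokine list split in vehicle, with 9 of 30 higher and 9 lower (camera adjusted p = 0.968), a median of 0.05 and a mean of -0.07. The oxidative phosphorylation list had 4 of 25 higher and 11 lower (camera adjusted p = 0.186) in vehicle. With vehicle 3579 genes were higher in KO and 3260 lower, 72 and 116 by over 2-fold. With agonists the counts were 3085 and 3136, 41 and 119 by over 2-fold. The treat test had 414 and 333 past 1.5-fold. Over 2-fold in both treatments were 33 higher and 88 lower genes, against 0.257 and 1.22 for independent lists.

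Ex3a OVX and ERKO OVX cells, which differ by the receptor after the same surgery, also differed in C1qa, C1qb and C1qc, which were higher in the arm without ERα. C1qa was at 116 FPKM in vehicle Ex3a OVX and 2.43 in vehicle ERKO OVX (5.09 ± 0.06, limma adjusted p = 3.57e-11). C1qb (4.94) and C1qc (4.79), the monocyte chemokines Ccl12 (4.32) and Ccl7 (4.22), Ms4a4c (3.77) and the interferon-induced GTPase Gbp11 (3.29) were higher too. Lower in Ex3a OVX were the detoxifying enzymes Gsta4 (-3.49), Nqo1 (-3.10) and Ptgr1 (-2.82), the carbonic anhydrase Car4 (-2.90), Stfa3 (-2.89) and the epithelial cytokine Il1f9 (-2.79). With agonists C1qb (5.09) and C1qa (4.61) and the antibody receptor Fcgr1 (3.20) were higher, and Il1f9 (-2.79) and Gsta4 (-2.73) lower. Gsta2 and Gsta4, Stfa2 and Stfa3, the Ear genes, the Serpinb genes and H2-Q7 belong to families of near-identical copies, so reads may have been split among them and their values are uncertain.

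Interferon-stimulated genes were higher in Ex3a OVX, with 32 of 32 higher and 0 lower (camera adjusted p = 4.40e-15, adjusted p = 0.173 with an estimated correlation) in vehicle, as in Ifit3 (1.63), Ifit2 (1.93) and Irf7 (0.87). With agonists they had 31 of 32 higher and 0 lower (camera adjusted p = 1.54e-14, adjusted p = 0.184 with an estimated correlation), as in Ifit3 (2.03). Ifnb1 (1.58) and Cxcl10 (2.35) were higher in vehicle as well. Sterol biosynthesis genes had 0 of 21 higher and 21 lower (camera adjusted p = 7.33e-14, adjusted p = 0.0217 with an estimated correlation) in vehicle, including Cyp51 (-1.63) and Sqle (-1.45). After agonists the sterol list had 0 of 21 higher and 19 lower (camera adjusted p = 9.40e-10, adjusted p = 0.0435 with an estimated correlation). Besides these, the only calls that held with an estimated correlation among all lists and comparisons given here were those of the sterol and IL-4 lists in KO against WT with agonists. Macrophage genes had 14 of 17 higher and 2 lower (camera adjusted p = 1.52e-06, adjusted p = 0.176 with an estimated correlation) in vehicle, as in Trem2 (2.11). After agonists the macrophage list had 14 of 17 higher and 1 lower (camera adjusted p = 9.99e-07, adjusted p = 0.189 with an estimated correlation). MHC class I genes had 13 of 14 higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 7.20e-07, adjusted p = 0.176 with an estimated correlation) in vehicle, as in H2-K1 (0.71) and Tap1 (0.67). After agonists the class I list had 14 of 14 higher and 0 lower (camera adjusted p = 2.13e-07, adjusted p = 0.189 with an estimated correlation). Glycolysis genes had 3 of 21 higher and 18 lower (camera adjusted p = 2.27e-08, adjusted p = 0.182 with an estimated correlation) in vehicle, as in Eno1 (-0.89) and Aldoa (-0.64). After agonists the glycolysis list had 2 of 21 higher and 18 lower (camera adjusted p = 2.47e-06, adjusted p = 0.271 with an estimated correlation). The endosomal TLR pathway had 14 of 20 higher and 4 lower (camera adjusted p = 0.00366, adjusted p = 0.176 with an estimated correlation) in vehicle, with Tlr9 (1.52) and Tlr7 (0.62) and the chaperone Unc93b1 (0.99) higher. With agonists it had 12 of 20 higher and 4 lower (camera adjusted p = 0.00798, adjusted p = 0.189 with an estimated correlation), with Tlr9 (1.54) and Unc93b1 (1.16) higher. Maturation genes had 5 of 20 higher and 15 lower (camera adjusted p = 0.00214, adjusted p = 0.475 with an estimated correlation) in vehicle, with the homing receptor Ccr7 (-1.28) lower. IL-4 response genes had 4 of 18 higher and 12 lower (camera adjusted p = 0.00453, adjusted p = 0.189 with an estimated correlation) with agonists, as in the chitinase-like Chil3 (-1.87). The estrogen response list had 11 of 16 higher and 2 lower (camera adjusted p = 0.00832, adjusted p = 0.176 with an estimated correlation) in vehicle, with Ccnd1 (2.66) higher and Irf4 (-1.50) lower. MHC class II genes had 8 of 12 higher and 3 lower (camera adjusted p = 0.0223, adjusted p = 0.176 with an estimated correlation) in vehicle, with the lysosomal proteases Lgmn (1.28) and Ctss (0.80) higher. Oxidative phosphorylation genes went opposite ways in the 2 treatments. They had 2 of 25 higher and 12 lower (3 and 12 adjusted over the list alone, camera adjusted p = 0.0485, adjusted p = 0.363 with an estimated correlation) in vehicle, as in Mdh2 (-0.46) and Cs (-0.31). After agonists the oxidative list had 16 of 25 higher and 2 lower (camera adjusted p = 0.00432, adjusted p = 0.271 with an estimated correlation), as in Sdhb (0.56) and Atp5o (0.37). With agonists, NF-kB feedback genes had 3 of 17 higher and 10 lower (3 and 11 adjusted over the list alone, camera adjusted p = 0.0377, adjusted p = 0.42 with an estimated correlation), as in Zc3h12a (-0.75) and Rel (-0.74). Markers of other cell types differed beside these groups. T and NK cell genes had 8 of 11 higher and 3 lower (camera adjusted p = 0.0316, adjusted p = 0.385 with an estimated correlation) in vehicle, as in Nkg7 (1.70) and Cd3g (1.42). After agonists the T and NK list had 8 of 11 higher and 3 lower (camera adjusted p = 0.0152, adjusted p = 0.344 with an estimated correlation). Mast cell and basophil genes had 1 of 9 higher and 7 lower (camera adjusted p = 8.49e-04, adjusted p = 0.176 with an estimated correlation) in vehicle, as in Fcer1a (-1.86) and Cpa3 (-1.67). After agonists the mast cell list had 0 of 9 higher and 7 lower (camera adjusted p = 0.00102, adjusted p = 0.189 with an estimated correlation). With vehicle 3312 genes were higher and 2957 lower in Ex3a OVX, 278 and 250 by over 2-fold. After agonists the counts were 3646 and 3474, 313 and 245 by over 2-fold. The treat test had 806 and 857 past 1.5-fold. Over 2-fold in both treatments were 212 higher and 177 lower genes, against 7.67 and 5.40 for independent lists. With vehicle, 33 genes over 2-fold lower in KO than in WT were over 2-fold higher in Ex3a OVX than in ERKO OVX, against 2.84 for independent lists. Another 27 were lower in both, against 2.56. C1qa was among those that went opposite ways. After agonists the numbers were 20 higher in Ex3a OVX, against 3.28, and 36 lower in both, against 2.56. Of the genes over 2-fold higher in KO, 22 were lower in Ex3a OVX and 2 higher with vehicle, against 1.59 and 1.76. With agonists 9 were lower and 3 higher, against 0.882 and 1.13.

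Across surgery states with the same ERα short receptor, vehicle cells of ERKO OVX differed from those of KO in most genes, and surgery, pellet and library depth change together in this comparison. The libraries stood apart in other ways too, which bear on every list below and on Ex3a OVX against WT. Xist, expressed from the inactive X chromosome, was at 54.8 to 66.5 FPKM in all unoperated libraries and 4.33 to 9.74 in all ovariectomized ones. Mir6236, a small RNA row left out of the tests, had group means of 267 to 2472 and 7764 to 12795 FPKM, and sums of FPKM per library were 481738 to 522287 and 612322 to 696321. Saa3 (chromosome 7, 46711998 to 46719615) was at 63.4 ± 0.321 FPKM in KO and 5028 in ERKO OVX (6.29 ± 0.07, limma adjusted p = 1.89e-11), and the iron-binding protein Lcn2 (6.07) was higher too. The basophil proteases Mcpt8 (5.72) and Prss34 (5.20) and the granule enzyme Mpo (4.58) of granulocyte precursors were among the largest rises. The matrix glycoproteins Thbs1 (-5.21) and Fn1 (-4.62), the retinoic acid synthase Aldh1a2 (-4.35) and the nuclear RNA Neat1 (-3.67) had some of the largest falls. The cytokine list had 25 of 30 higher and 2 lower (26 and 2 adjusted over the list alone, camera adjusted p = 1.20e-05, adjusted p = 0.211 with an estimated correlation), as in Ccl3 (2.82), Il12a (2.68) and Il6 (1.68). Interferon-stimulated genes had 26 of 32 higher and 5 lower (camera adjusted p = 7.22e-06, adjusted p = 0.211 with an estimated correlation), as in Irf7 (2.33) and Ifit3 (2.54). MHC class II genes had 10 of 12 higher and 1 lower (camera adjusted p = 3.51e-04, adjusted p = 0.198 with an estimated correlation), as in H2-Ab1 (2.24). MHC class I genes had 11 of 14 higher and 2 lower (camera adjusted p = 0.00568, adjusted p = 0.322 with an estimated correlation), as in B2m (1.16). Oxidative phosphorylation genes had 25 of 25 higher and 0 lower (camera adjusted p = 9.92e-08, adjusted p = 0.198 with an estimated correlation), as in Sdhb (1.23) and Atp5o (0.84). Glycolysis genes had 16 of 21 higher and 2 lower (camera adjusted p = 2.36e-04, adjusted p = 0.307 with an estimated correlation), as in Eno1 (1.12) and Tpi1 (1.02). Sterol biosynthesis genes had 13 of 21 higher and 4 lower (camera adjusted p = 0.0306, adjusted p = 0.211 with an estimated correlation), with Fdps (0.96) higher and Idi1 (-1.19) lower. Macrophage genes had 12 of 17 higher and 3 lower (camera adjusted p = 0.00411, adjusted p = 0.307 with an estimated correlation), with Marco (4.01) and Emr1 (3.56) higher. Maturation genes had 3 of 20 higher and 15 lower (camera adjusted p = 4.72e-04, adjusted p = 0.389 with an estimated correlation), with Ccr7 (-1.80) and Relb (-1.55) lower. Markers of other cell types moved too. Mast cell and basophil genes had 8 of 9 higher and 0 lower (camera adjusted p = 1.60e-04, adjusted p = 0.211 with an estimated correlation), as in Cpa3 (4.09). Neutrophil and granulocyte precursor genes had 15 of 18 higher and 3 lower (camera adjusted p = 2.04e-04, adjusted p = 0.211 with an estimated correlation), as in Ctsg (3.68). Of the 27 tested genes of these 2 lists, 12 passed the filter on low values only through ovariectomized libraries. Such genes could hardly come out lower, so the counts and p-values of both lists follow in part from the filter. How many genes of the other lists passed in this way was not counted. T and NK cell genes had 10 of 11 higher and 0 lower (camera adjusted p = 5.71e-04, adjusted p = 0.237 with an estimated correlation), as in Thy1 (3.42) and Gzmb (2.91). Fibroblast and stroma genes had 5 of 9 higher and 0 lower (camera adjusted p = 0.0108, adjusted p = 0.307 with an estimated correlation), as in Lox (4.81), which agonists raised in all 4 arms. In all 4648 genes were higher and 4527 lower in ERKO OVX, 679 and 788 by over 2-fold. The treat test placed 2635 past 1.5-fold.

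Vehicle cells of Ex3a OVX differed from WT by receptor, surgery, pellet and depth at once. The interferon-induced Cxcl10 (5.62) went from 3.16 ± 0.480 FPKM in WT to 203 in Ex3a OVX (limma adjusted p = 7.38e-08). Plac8 (6.75), Ms4a4c (6.18), Saa3 (5.29) and Marco (4.88) and the cytotoxic granule protease Gzmb (4.85) were higher. Retnla went from 175 ± 2.20 to 0.275 FPKM (-7.11 ± 0.04) and Arg1 from 262 ± 0.465 to 2.79 FPKM (-6.12 ± 0.08). Thbs1 (-5.76) and Fn1 (-5.32) were lower as well. Interferon-stimulated genes had 31 of 32 higher and 1 lower (camera adjusted p = 1.79e-11, adjusted p = 0.181 with an estimated correlation), as in Ifit3 (4.43) and Irf7 (3.10). Cytokines and chemokines had 27 of 30 higher and 1 lower (camera adjusted p = 3.83e-06, adjusted p = 0.199 with an estimated correlation), as in Cxcl11 (2.76) and Il12a (2.67). MHC class II genes had 11 of 12 higher and 0 lower (camera adjusted p = 2.94e-05, adjusted p = 0.119 with an estimated correlation), as in H2-Ab1 (3.18) and H2-Eb1 (2.66). MHC class I genes had 13 of 14 higher and 1 lower (camera adjusted p = 2.67e-05, adjusted p = 0.205 with an estimated correlation), as in B2m (1.49). Macrophage genes had 14 of 17 higher and 1 lower (camera adjusted p = 5.69e-05, adjusted p = 0.205 with an estimated correlation), as in Emr1 (3.23) and Vcam1 (4.13). Maturation genes had 5 of 20 higher and 14 lower (camera adjusted p = 0.0178, adjusted p = 0.487 with an estimated correlation), as in Ccr7 (-2.43). Cell cycle genes had 28 of 30 higher and 2 lower (camera adjusted p = 1.96e-05, adjusted p = 0.298 with an estimated correlation), with Birc5 (2.05) higher and Mki67 (-1.62) lower. Oxidative phosphorylation genes had 23 of 25 higher and 1 lower (camera adjusted p = 1.63e-05, adjusted p = 0.194 with an estimated correlation), as in Sdhb (1.38). Sterol biosynthesis genes had 4 of 21 higher and 14 lower (camera adjusted p = 0.0178, adjusted p = 0.199 with an estimated correlation). Glycolysis genes had 2 of 21 higher and 17 lower (camera adjusted p = 0.00324, adjusted p = 0.425 with an estimated correlation). IL-4 response genes had 3 of 18 higher and 15 lower (camera adjusted p = 4.40e-05, adjusted p = 0.119 with an estimated correlation), as in Tgm2 (-2.66). Markers of other cell types were higher beside these groups. T and NK cell genes had 11 of 11 higher and 0 lower (camera adjusted p = 5.45e-05, adjusted p = 0.199 with an estimated correlation), as in Nkg7 (2.96) and Gzma (3.41). Mast cell and basophil genes had 7 of 9 higher and 0 lower (camera adjusted p = 0.00191, adjusted p = 0.199 with an estimated correlation), as in Prss34 (4.80) and Mcpt8 (4.18). Neutrophil and granulocyte precursor genes had 15 of 18 higher and 3 lower (camera adjusted p = 7.42e-04, adjusted p = 0.199 with an estimated correlation), as in Mpo (4.05) and Ctsg (3.38). The limit given above for the 12 genes of these 2 lists that passed the filter only through ovariectomized libraries holds here too. In all 4718 genes were higher and 4643 lower, 822 and 830 by over 2-fold. The treat test placed 2882 past 1.5-fold. Over 2-fold in both comparisons across surgery were 368 higher and 496 lower genes, against 49.2 and 57.6 for independent lists.

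**Figure D3:**
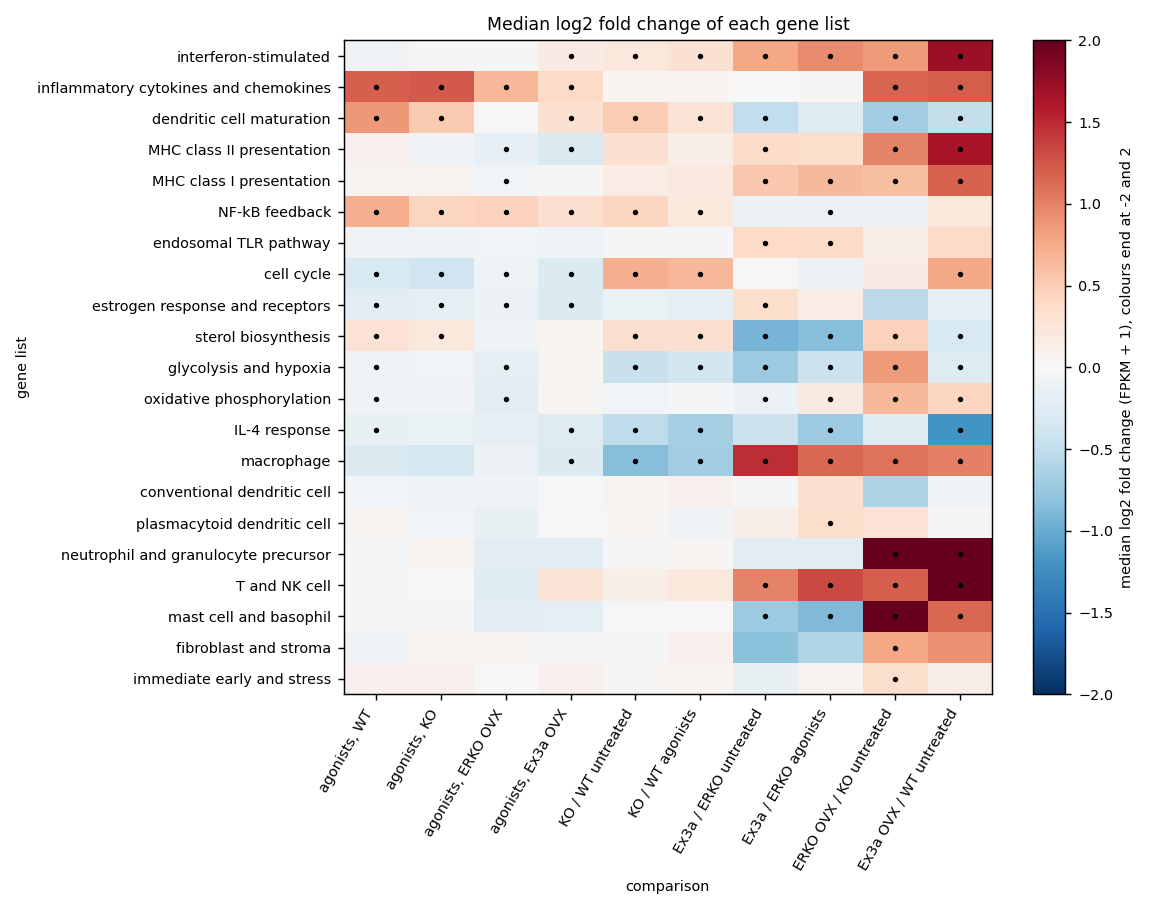
Median log2 fold change (log2(FPKM + 1) scale; colours end at -2 and 2) of 21 gene lists (vertical) in 10 comparisons (horizontal), with a dot where the camera adjusted p was below 0.05. Interferon-stimulated genes had a median of 0.77 in vehicle Ex3a OVX against ERKO OVX and 1.71 against WT, and mast cell and basophil genes one of 2.99 in vehicle ERKO OVX against KO.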

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

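The comparison of the agonist response between ERKO OVX and KO, and both tests of explanations in this part, were chosen after the results were seen, while the other interaction tests were set before.

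The agonist response differed in 790 genes between KO and WT and in 3560 between Ex3a OVX and ERKO OVX. It differed in 2702 between ERKO OVX and KO, which carry the same ERα short receptor and differ by surgery and pellet. Each stands here because a difference between arms under the same treatment was past a test. All 4 groups in the comparison of Ex3a OVX with ERKO OVX and 2 of 4 in that of ERKO OVX with KO are 1 sample each, so both counts rest on the spread of the WT and KO libraries, and the spread between ovariectomized cultures was not measured.

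In the comparison of ERKO OVX with KO, 1290 genes had a more positive and 1412 a more negative response in ERKO OVX, 18 and 56 by over 2-fold, and 55 were past 1.5-fold in limma's treat test. The acute phase genes Saa3 (-3.15) and Lcn2 (-2.73), the prostaglandin synthase Ptgs2 (-2.59) and the cytokines Il12b (-2.32), Il1b (-1.96), Ccl3 (-1.94), Tnf (-1.71) and Il6 (-1.05) rose less in ERKO OVX. The monocyte receptor Ccr2 (1.22) and the protease Mmp19 (1.26) were more positive. The cytokine list had 3 of 30 more positive and 18 more negative (5 and 20 adjusted over the list alone, camera adjusted p = 4.54e-07) and maturation genes 0 of 20 more positive and 15 more negative (2 and 15 adjusted over the list alone, camera adjusted p = 2.55e-08, adjusted p = 0.25 with an estimated correlation for both), as in Fscn1 (-1.02) and Cd70 (-1.73). NF-kB feedback genes had 0 of 17 more positive and 11 more negative (0 and 12 adjusted over the list alone, camera adjusted p = 1.17e-04, adjusted p = 0.25 with an estimated correlation), as in Socs3 (-1.46) and Nfkbiz (-1.27), and sterol biosynthesis genes 1 of 21 more positive and 13 more negative (1 and 14 adjusted over the list alone, camera adjusted p = 1.70e-06, adjusted p = 0.105 with an estimated correlation), as in Idi1 (-0.75). More negative too were MHC class I genes with 0 of 14 more positive and 10 more negative (camera adjusted p = 2.22e-05), as in Psmb8 (-0.36). Oxidative phosphorylation genes had 0 of 25 more positive and 13 more negative (0 and 19 adjusted over the list alone, camera adjusted p = 7.91e-07), as in Cs (-0.26). Neutrophil and granulocyte precursor genes had 1 of 18 more positive and 9 more negative (camera adjusted p = 1.71e-05), as in Camp (-1.14). Mast cell and basophil genes had 0 of 9 more positive and 5 more negative (camera adjusted p = 0.0214), as in Prss34 (-0.57), at 0.042 FPKM in both KO groups. Of the last 2 lists, 12 genes passed the filter only through ovariectomized libraries, so they were too low in KO to compare. These lists, from MHC class I on, had adjusted p = 0.25 with an estimated correlation. Glycolysis genes had 1 of 21 more positive and 5 more negative (1 and 6 adjusted over the list alone, camera adjusted p = 0.0214, adjusted p = 0.546 with an estimated correlation), as in Tpi1 (-0.18), and immediate early and stress genes 2 of 19 more positive and 7 more negative (3 and 9 adjusted over the list alone, camera adjusted p = 0.0399, adjusted p = 0.25 with an estimated correlation), as in Hspa1b (-0.86). Cell cycle genes went the other way, with 16 of 30 more positive and 1 more negative (17 and 1 adjusted over the list alone, camera adjusted p = 7.70e-06, adjusted p = 0.281 with an estimated correlation), as in Ccne2 (0.91), and a mean change after agonists of -0.14 in ERKO OVX and -0.41 in KO. Estrogen response genes had 5 of 16 more positive and 2 more negative (6 and 2 adjusted over the list alone, camera adjusted p = 0.0793), as in Vegfa (1.04), with means of -0.18 and -0.39.

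Among genes that rose more than 2-fold in WT, agonist responses were smaller in both ovariectomized arms, a choice of genes that favours WT. Over the 101 of these 178 with a mean above 20 FPKM, the median ratio to the WT log2 change was 0.3559 in ERKO OVX, 0.3012 in Ex3a OVX and 0.8127 in KO. Over 77 genes chosen the same way in KO it was 0.3915, 0.3787 and 0.9516, and over genes chosen in the ovariectomized arm itself 0.4933 in ERKO OVX (19 genes) and 0.5853 in Ex3a OVX (21 genes), which argues against shallower sequencing as the whole cause, since well-covered genes should then have responded as in WT. The median vehicle level over both arms lay 0.6204 of the way from vehicle to treated WT. A candidate explanation is that these cells were already partly at the treated level. The place was 0.7649 in ERKO OVX (119 of 178 genes past the middle), 0.457 in Ex3a OVX (85, short of the middle) and 0.1875 in KO (33). With genes chosen in KO it was 0.894, 0.7848 and 0.1223. Chosen in the arm itself it was 0.7329 in ERKO OVX and 1.046 in Ex3a OVX, where treated WT was no ceiling. Surgery, pellet and a separate culture or sequencing run go together here and stay open and untested.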

How the results depend on the processing

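Chosen after the data were seen were the tests with 16 libraries, median-of-ratios scaling, a 5 FPKM filter, small RNA rows kept, crossed pairing, a replicate block with 16 libraries, the comparison of the response of ERKO OVX with KO, and the agonist response over genes chosen in other arms than WT, given with that pattern. Because the values are FPKM, the alternatives that need counts (edgeR with other size factors or library size alone, DESeq2, and filters on counts) were not run. A fit of the compared groups alone was not run for comparisons with ovariectomized groups, which hold 1 sample each.

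Of the gene and list counts under the alternatives, 317 stayed within 1.5 times the reported one, 32 were lower and 19 higher than that. In the order agonists in WT, KO, ERKO OVX and Ex3a OVX, KO against WT in vehicle and agonists, Ex3a OVX against ERKO OVX in vehicle and agonists, interaction of KO and WT, interaction of Ex3a OVX and ERKO OVX, ERKO OVX against KO, Ex3a OVX against WT, and interaction of ERKO OVX and KO, the counts were as follows. A change over 1.5-fold (limma's treat test, a stricter question by construction) left 524, 358, 31, 84, 414, 333, 806, 857, 5, 26, 2635, 2882 and 55 genes. The number of genes past the test and over 2-fold, 268, 193, 32, 75, 188, 160, 528, 558, 6, 52, 1467, 1652 and 74 as reported, was 505, 405, 96, 195, 435, 373, 836, 929, 17, 192, 2180, 2433 and 178 with 0.1 FPKM added and 122, 83, 20, 32, 83, 75, 291, 310, 4, 17, 693, 797 and 31 with 5, because a larger addition shrinks fold changes of low genes by construction. With the correlation estimated for each list, 0, 0, 0, 0, 0, 2, 1, 1, 0, 0, 0, 0 and 0 of 21 lists were past the threshold. With fry, directional, which tests whether a list moves at all and not against other genes, 15, 15, 14, 19, 16 and 19 lists were past it for agonists in WT, KO and Ex3a OVX, KO against WT in both treatments and Ex3a OVX against ERKO OVX with agonists. With fry, mixed, 20, 21, 21, 21, 21, 21, 21, 21, 18 and 21 lists were past it in the leading 10 comparisons and 21 in the last.

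With 16 libraries as separate samples, the interaction of Ex3a OVX and ERKO OVX had 5534 genes in place of 3560. That fit both lets in the spread of the ovariectomized pairs and gives each of these groups 2 samples, and which of these raised the count was not tested. The other counts were 6337, 5638, 6012, 5973, 6611, 5999, 7533, 8145, 1018, 9439, 9627 and 3899, all within 1.5 times, and 4245 of the 4258 agonist calls in ERKO OVX were shared. The interaction of KO and WT fell from 790 to 404 genes without a filter on low values, and to 431 to 651 with single libraries left out. The count was 433 and 498 without KO vehicle libraries 1 and 2, 431 without either WT vehicle library and 485 without WT agonist library 2, where the lone library was assumed to vary like the other groups. The cause was not tested. In the other comparisons, in the order above, leaving out single libraries gave 5462 to 5671, 4756 to 5020, 4387 to 4397, 4307 to 4467, 5808 to 5881, 5156 to 5474, 6316 to 6400, 7136 to 7215, 3642 to 3706, 8775 to 9180, 8971 to 9381 and 2082 to 2851 genes. Among named genes, 21865 values under alternatives kept direction and call, 1098 lost the call, 134 gained it and 1 was reversed: Tnf in KO against WT with vehicle (0.08, not past the test) was -0.2191 without WT vehicle library 1 and 0.375 without library 2, both past the test (limma adjusted p = 0.0283 and 0.00218). The 2 libraries held 11.3 and 17.6 FPKM.

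The library numbers did not pair the libraries by this check. Deviations of same-numbered libraries correlated across genes at -0.011 (WT, vehicle with agonists), -0.053 (KO, the same), -0.030 (KO with WT, vehicle) and -0.193 (KO with WT, agonists), and in the ovariectomized arms at 0.017 (ERKO OVX, vehicle with agonists), 0.017 (Ex3a OVX, the same), -0.010 (both arms, vehicle) and -0.026 (both arms, agonists). With the replicate block, agonists in WT and KO, KO against WT in vehicle and agonists and their interaction had 6262, 5577, 6474, 5845 and 558 genes. Crossing the numbers gave 6315 for KO against WT with agonists. In the other comparisons an averaged pair left no numbers to block on. With 16 libraries the replicate block gave 6042, 6025, 7523, 8174, 5572, 9432, 9614 and 3776 genes there, in the order above, against 6012, 5973, 7533, 8145, 5534, 9439, 9627 and 3899 without it. In simulated data 1.3-fold changes were recovered in 52% of genes for agonists in ERKO OVX and 49% for the interaction of KO and WT, so a gene that missed these tests is not shown to be unchanged. The effect of depth on low genes was not tested.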

Other observations

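The tests of other cell types, depth and sequencing run in this part were chosen after the results were seen, and those of the DNA around Esr1 were not.

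Conventional dendritic cell genes went both ways between the arms. In vehicle ERKO OVX against KO the list had 3 of 11 higher and 7 lower (camera adjusted p = 0.15), with the lineage factor Zbtb46 (-2.14) and Cd24a (-1.14) lower. In vehicle Ex3a OVX against WT it had 4 of 11 higher and 5 lower (camera adjusted p = 0.559), with Zbtb46 (-1.94) lower and the adhesion gene Cadm1 (1.48) higher. In vehicle Ex3a OVX against ERKO OVX it had 4 of 11 higher and 4 lower (camera adjusted p = 0.897), with Irf8 (0.78) and Amica1 (1.71) higher and the CD11c gene Itgax (-0.83) lower. Plasmacytoid dendritic cell genes had 7 of 11 higher and 1 lower (camera adjusted p = 0.0454, adjusted p = 0.288 with an estimated correlation) in Ex3a OVX against ERKO OVX with agonists, as in the tetherin gene Bst2 (0.69) and Ly6d (0.93), and the monocyte-shared Ly6c2 (3.85) was higher in vehicle ERKO OVX than in KO.

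Immediate early and stress genes had 13 of 19 higher and 4 lower (camera adjusted p = 0.0283, adjusted p = 0.211 with an estimated correlation) in vehicle ERKO OVX against KO, with the heme oxygenase Hmox1 (1.55) and the stress factors Ddit3 (1.56) and Trib3 (1.78) higher, and Hmox1 was lower in vehicle KO than in WT (-2.60). Fibroblast and stroma genes had 4 of 9 higher and 5 lower (camera adjusted p = 0.361) in vehicle Ex3a OVX against ERKO OVX, with Lox (-1.90) and Col5a1 (-1.89) lower and Col1a2 (0.92) higher. B cell, eosinophil and erythroid lists had 3, 4 and 2 tested genes, too few for camera. In vehicle ERKO OVX against KO the B cell genes Cd79b (2.0), Mzb1 (0.76) and Igj (0.62) were higher. Of the eosinophil genes Prg2 (0.98) was higher and Siglec5 (-0.73) and Ear1 (-0.18) were lower, and of the erythroid genes Car2 (0.60) was higher and Tfrc (-0.24) lower.

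Basophil, mast cell and granulocyte precursor genes were higher in both ovariectomized arms than in the unoperated ones. In vehicle ERKO OVX and Ex3a OVX, Mcpt8 was at 52.6 and 18.8 FPKM, Prss34 at 37.3 and 27.5 and Mpo at 24.0 and 16.2, all below 0.15 in vehicle WT and KO libraries, so that 3.0 of 5 abundant transcripts passed 5 FPKM in both, while Cpa3 (16.05 and 4.36) and Elane (1.28 and 1.02) did not. The medians of 27 list genes were 2.60 and 2.135 log2 units higher in the ovariectomized arms, whose libraries are shallower. Of the 15 past the filter in unoperated libraries alone, 12 were higher in each (medians 2.33 and 1.755, lower quartiles 0.62 and 0.09). This repeats the pattern without the 5 transcripts above, so depth stays open. Basophils or precursors in the cultures, which a gate on high CD11c should remove if one was used, may be a source. Run, surgery and pellet cannot be told apart, as the depth ranges of the 2 surgery states do not overlap (lowest over highest 1.565).

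Genes over 2-fold apart in both treatments between KO and WT lay near Esr1 more often than other genes. Of 121 such genes, 4 (Arg1, Perp, Plekhg1 and Sash1) lay within 20 Mb of Esr1 on chromosome 10, against 68 of 11153 others (odds ratio 5.571, 95% interval 1.452 to 15.31, Fisher's exact p = 0.007409, 2-sided). Flanking DNA of another strain carried with the targeted allele may account for these 4. The other 117 lay outside this window, where carried DNA was not tested. For Ex3a OVX against ERKO OVX, 2 of the 384 with a known position among 389 such genes (D10Bwg1379e and Stx11) lay there, an odds ratio of 0.8093 (0.09577 to 3.055) that leaves it open, as both arms carry a targeted allele. The receptor itself as the cause of the 4 differences stays open and untested.

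The Y-linked Ddx3y, Kdm5d and Eif2s3y were listed at 0 in all 16 libraries. The 2 KO vehicle libraries held 745 and 4198 FPKM of Mir6236, the small RNA that was higher in the ovariectomized libraries.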
